A study of Homo sapiens with 19 samples.

How the data were processed

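RNA was measured in 18 patient-derived xenografts of breast cancer and in 1 patient tumour. Per the labels' protocols, tumour fragments or cell suspensions were grown in mammary fat pads of immunodeficient mice, tumours were flash frozen, and total RNA was made into libraries with a strand-marking kit after removal of ribosomal RNA and sequenced as single reads. Per the submitters' processing notes, the tools included STAR 2.5.2b and the builds hg38 and GRCh38. The counting program, the annotation release, its strand setting and the treatment of mouse reads are not given in the sources used here. Reads of a human gene and of its mouse counterpart, of near-identical copies, of overlapping genes or of antisense partners may therefore be mixed in a count. This concerns the ribosomal protein, histone, MAGE and UGT2B families, TRIM43, ROPN1, KRT6A and KRT6B, and the overlapping pair KRT8 and KRT18, whose values are uncertain to that extent.

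The deposited table holds whole-number counts per gene, not normalised by the authors as far as the values show. It lists 58302 Ensembl gene identifiers, of which 58039 were found in GENCODE v29 on GRCh38, the source of all symbols and coordinates given here. Before every step 1234 genes were removed because their levels can reveal something about a donor: XIST, TSIX, Y-linked genes, HLA genes, immunoglobulin and T cell receptor segments, killer-cell immunoglobulin-like receptors and genes with common null alleles. They took at most 1.492% of a library's counts. The remaining 57068 genes were used. Some items that met the rule for named genes are not reported here. Libraries held 18620825 to 104012848 counts, with a median of 35097550.

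Libraries were grouped by the line code in the labels. The codes are replaced by the letters A to J. The labels do not say that libraries of a line came from separate animals, so p-values measure the spread between libraries of a line, which may be technical in part, and not between donors. As a check for mixed-up samples, each of the 12 libraries of the replicated lines was set against the libraries of all other groups. 1 library did not match its group's labels, in that it resembled another group as closely as some replicates of a line resembled each other. This library was kept in its labelled group, whose values therefore rest in part on a library of doubtful identity. The comparisons of the other replicated lines with that group, and the similarity test, rest on it in part as well.

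The counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling and a quasi-likelihood fit over the 12 libraries of lines A, C, D and E, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of the genes, 23562 passed the filter. A line was compared with the unweighted mean of the other 3 lines on the log2 scale, so a log2 fold change weighs the other lines equally on that scale and can differ from a ratio of pooled counts. The Luc2 comparison used the 8 Luc2 or untagged libraries of lines A, C and E with the line as a block, and 20812 genes. An error after a log2 fold change is its standard error, and an error after CPM, the usual depth-scaled count, is the SD between libraries. CPM in the line comparisons were TMM-scaled over the 12 libraries. Levels across all lines and in the patient comparison were TMM-scaled over all 19, which shifts them slightly.

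Gene lists fixed before the data were examined were tested with camera in limma 3.58.1, with its preset inter-gene correlation and, beside it, with an estimated one. A p is adjusted over the lists of a comparison. The 28 lists were luminal lineage, oestrogen receptor targets, basal and myoepithelial, ERBB2 neighbourhood on 17q12, apocrine genes, proliferation, mesenchymal programme, epithelial junctions, interferon response, antigen processing, hypoxia and glycolysis, cholesterol synthesis, p53 targets, G1 to S regulators, MYC programme, cancer-testis antigens, secretory and mammary differentiation, immediate early, heat shock and unfolded protein, mitochondrially encoded, replication-dependent histones, cytosolic ribosomal proteins, and markers of fibroblasts, endothelium, macrophages and myeloid cells, T and natural killer cells, B and plasma cells, and adipocytes. PGR and TFF1 stand in both of the first 2 lists, and some other genes also stand in more than 1 list, such as SPDEF in the luminal and apocrine lists and LOX in the mesenchymal and hypoxia lists. None of the marker lists of other cell types shares a gene with another list. Some fixed symbols were 2 names of the same gene, so 22 interferon response symbols gave 21 genes and 20 histone symbols gave 13. Of 14 adipocyte symbols 13 were matched, and TNMT was not.

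Named genes followed a rule fixed before the data were examined. It took a panel of 20 breast cancer genes, the 8 protein-coding genes with the largest rise and the 6 with the largest fall in each line (adjusted p under 0.05, at least 10 CPM in the higher side, every library of the line beyond every library of the other lines), and up to 3 members of each list called. In the patient comparison it took the 8 largest rises and 8 largest falls with at least 20 CPM in the higher library. For genes at or near 0 counts in a group, a ratio of pooled counts is given with an exact 95% interval, and where a group had 0 counts a lower bound was computed with 3 counts over that group. These intervals and bounds cover counting error only.

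Similarity was the Pearson r of log2(CPM + 1) across genes, tested by 100000 random permutations of the line labels with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. The patient tumour and its xenograft were compared by the log2 ratio of CPM + 0.5 over 28597 genes, without a test, and list medians were set against 10000 random lists of the same size matched on mean expression. Alternatives were DESeq2 1.42.0 and its size factors, other filters on low counts, a test against a 2-fold change, library sizes without mitochondrial and small RNA genes, all 19 libraries in the fit, the tag as a covariate, and leaving out each library. Fits without line A, without line A and the Lucs library, and of Luc2 in lines C and E only were added after the data had been seen. The fits were tested on simulated data with 100 changed genes at each of 2 sizes. Far more genes passed in the real line comparisons, where the adjusted threshold is therefore less strict. The shares recovered need not hold for those comparisons. At 4-fold changes 45% of the changed genes were recovered in line A, 66% in line C, 66% in line D and 60% in line E. At 2-fold changes 4% to 10% were recovered. For Luc2 the shares were 25% and 1%.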

Results

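Expression of human genes was measured by RNA sequencing in 19 breast cancer libraries. Of these, 18 were patient-derived xenografts, human tumours grown in the mammary fat pads of immunodeficient mice, and 1 was a patient tumour that shares its line code with xenograft line J. The xenografts came from 10 lines, here called A to J. Line A had 2 libraries, lines C and D had 3 each, line E had 4, and lines B, F, G, H, I and J had 1 each. The tag name Luc2 stood in the labels of 5 libraries, 1 of line A, 2 of line C and 2 of line E. Lucs stood in the label of 1 library of line E, and 13 libraries carried no tag. Total counts were 30915269 and 104012848 in line A, 24115797, 25954320 and 18620825 in line C, 32570652, 35687486 and 21934903 in line D, and 30959281, 33453279, 56217572 and 37171811 in line E. The single libraries held 41643796 (B), 37017793 (F), 41396562 (G), 35097550 (H), 40351585 (I) and 35524407 counts (J), and the patient tumour 25954302. Values of these single libraries have no replicate error.

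Whether tumours of a line resembled each other was asked first. Libraries of one line correlated across genes at a mean r of 0.975 over 13 pairs, and libraries of different lines at 0.841 over 53 pairs. The difference of 0.134 was larger than in all but few relabellings of the 12 libraries (one-sided permutation test, p = 2e-05). Genes are not independent replicates, so the test permuted libraries. Mean r was 0.966 in line C, 0.994 in line D and 0.979 in line E, and the 2 libraries of line A correlated at 0.913. Without the Luc2 and Lucs libraries the difference was 0.150 with p = 0.0501, and the 6 libraries left allow no permutation p below 0.05. Only line D kept pairs within the line, so this difference says nothing of similarity within lines A, C or E.

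The line comparisons then asked which genes set each replicated line apart. Expression of 17528 of 23562 genes differed among lines A, C, D and E (edgeR quasi-likelihood F-test, adjusted p under 0.05). Luminal and basal genes were among those that moved in opposite directions. Luminal lineage genes were higher in lines C and D and lower in lines A and E, and the test of that list held in all 4 with an estimated correlation. Basal and myoepithelial genes went the other way in each line, but with an estimated correlation that list held in line A alone. Each line is set against the mean of the other 3, so a rise in some lines entails a fall in others. The calls of the 4 lines are therefore not independent. Without line A, 16858 genes differed among the remaining 3 lines.

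**Figure D1:**
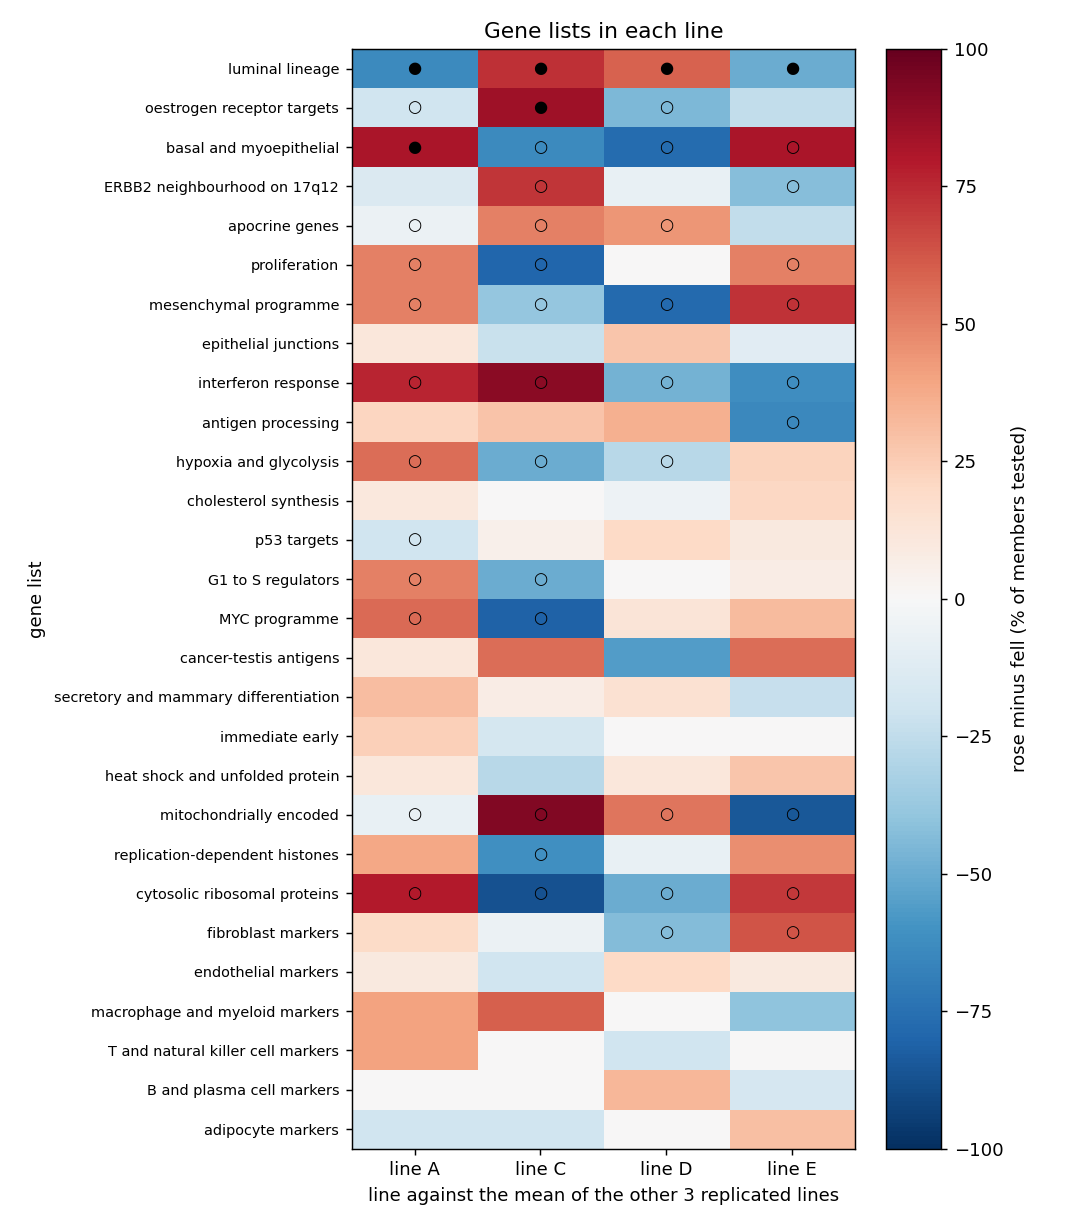
Gene lists in lines A, C, D and E, each against the mean of the other 3 lines. Colour gives the members that rose minus those that fell, as a percentage of the members tested, a circle marks a list called with the preset correlation (camera, adjusted p under 0.05) and a filled circle one also called with an estimated correlation. The luminal lineage row is marked with filled circles in all 4 lines, with 18 of 22 members raised in line C and 16 lowered in line A.

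Line C was set apart by hormone receptor genes. ESR1, which encodes oestrogen receptor alpha (ENSG00000091831, chromosome 6, 151656691 to 152129619, plus strand), reached 482 ± 160 CPM (SD, n = 3), against 4.17 in line A, 3.92 in line D and 4.5 in line E (log2 fold change 6.85 ± 0.37, edgeR adjusted p = 2.46e-07). The progesterone receptor gene PGR rose by 5.83 ± 0.24 on the log2 scale to 185 ± 29 CPM, and the luminal transcription factor genes GATA3 and FOXA1 rose by 5.08 ± 0.26 and 4.26 ± 0.48. In contrast, EGFR, the epidermal growth factor receptor gene, stood at 0.786 ± 0.88 CPM against 99.1 to 356 in the other lines (log2 fold change -7.69 ± 0.65), and VIM, which encodes the intermediate filament vimentin (chromosome 10, 17228259 to 17237593, plus strand), at 3.1 ± 3.0 CPM (-6.91 ± 0.69). Among the 20 panel genes 8 rose, 9 fell and 3 did not pass, the last being ERBB2 (0.48 ± 0.22), CDH1 (0.22 ± 0.17) and KRT14 (-1.84 ± 0.82).

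Of the 22 luminal lineage genes, 18 rose and 2 fell in line C (18 and 3 adjusted over the list alone, camera adjusted p = 7.64e-11, and adjusted p = 0.00179 with an estimated correlation). Of the 20 oestrogen receptor targets, 17 rose and none fell (18 and none adjusted over the list alone, adjusted p = 2.63e-14, and adjusted p = 0.0198 with an estimated correlation). They included the oestrogen-responsive genes GREB1 at 1590 ± 1100 CPM (log2 fold change 7.48 ± 0.50) and PDZK1 at 200 ± 210 CPM (10.01 ± 0.79), and TFF1, a secreted trefoil peptide gene (7.96 ± 0.87). Per the labels' protocols, oestrogen was given to mice in oestrogen receptor-positive cases, without naming the lines. Of 21 interferon response genes 19 rose, among them IFI27 (6.47 ± 0.69), XAF1 and MX2 (19 adjusted over the list alone, adjusted p = 2.5e-05, and adjusted p = 0.481 with an estimated correlation). Of 24 proliferation genes 19 fell, among them RRM2, a ribonucleotide reductase subunit (-2.52 ± 0.23), and MCM7, a replication helicase subunit (-1.97 ± 0.21), and none rose (19 adjusted over the list alone, adjusted p = 4.85e-08, and adjusted p = 0.299 with an estimated correlation).

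Basal and myoepithelial genes fell in line C in 15 of 22 cases and rose in 1 (the same counts adjusted over the list alone, adjusted p = 2.81e-06, and adjusted p = 0.27 with an estimated correlation), with TRIM29 at -6.19 ± 0.62. Of 24 cytosolic ribosomal protein genes 21 fell (23 adjusted over the list alone), with a median log2 fold change of -1.81, and a fall of the list as a whole (adjusted p = 4.85e-08, and adjusted p = 0.481 with an estimated correlation). RPS6 (chromosome 9, 19375715 to 19380254, minus strand) stood at 106 ± 27 CPM against 299 to 3890 in the other lines. Of 13 mitochondrially encoded genes 12 rose (13 adjusted over the list alone, adjusted p = 0.00469, and adjusted p = 0.67 with an estimated correlation). In the line C libraries RN7SL2, a signal recognition particle RNA, took 10.694%, 12.569% and 8.872% of all counts, and MALAT1, a nuclear RNA, took 5.944%, 6.811% and 4.458%. No other library had more than 3.786% in RN7SL2 or 4.065% in MALAT1. Further lists called were the MYC programme (none rose and 13 of 16 fell), the histones (8 of 13 fell), hypoxia and glycolysis (1 rose and 10 of 18 fell), G1 to S regulators (1 rose and 8 of 14 fell), the mesenchymal programme (7 of 18 fell), the ERBB2 neighbourhood (10 of 14 rose) and the apocrine list (10 of 16 rose and 2 fell), at adjusted p of 3.24e-05 to 0.0344, and adjusted p = 0.349 to 0.481 with an estimated correlation. Adjusted over the list alone these counts were the same except for 14 falls in the MYC programme, 9 falls among the G1 to S regulators and 11 rises in the ERBB2 neighbourhood.

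The largest rises in line C included that of MALRD1 (ENSG00000204740, chromosome 10, 19048771 to 19790401, plus strand) at 586 ± 170 CPM, 4107-fold above the pooled other lines (95% interval 3131 to 5499). The chemokine gene CXCL13, the growth factor gene FGF10, the cancer-testis antigen gene MAGEC2, PHGR1, UGT2B4, GTSF1 and PGLYRP2 also met the rule, but 6 of these 7 had SDs above their means, as in CXCL13 at 113 ± 160 CPM. KIF26A, MATK and TDRD1 had 0 counts in line C and were at least 350-fold, 332-fold and 375-fold lower than in the other lines. BEND7 had 3 counts, 992-fold lower (339 to 4811), LRIF1 had 2 counts and ZFP28 had 1. In all, 6003 genes rose and 5446 fell. Without line A, 11531 genes passed in place of 11449, the apocrine and mesenchymal lists lost their calls (adjusted p = 0.325 and 0.108), and so did the fall of MYC (from -1.33 ± 0.22 to -0.32, adjusted p = 0.238). The apocrine list was also lost without either library of line A (adjusted p = 0.051 without replicate 1 and 0.349 without replicate 2), and the hypoxia list without line A and the Lucs library (0.0582).

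Line D combined low ESR1 with high levels of luminal genes. ESR1 stood at 3.92 ± 0.15 CPM (SD, n = 3), while GATA3 reached 163 ± 2.3 CPM (log2 fold change 3.48 ± 0.25, edgeR adjusted p = 2.49e-06) and FOXA1 rose by 2.99 ± 0.46 on the log2 scale. TFF3, a secreted trefoil peptide gene (chromosome 21, 42311667 to 42315651, minus strand), reached 2640 ± 850 CPM (8.01 ± 1.00). MYC fell to 5.01 ± 0.83 CPM against 21.1 to 220 in the other lines (-4.10 ± 0.26). KRT5, a basal keratin gene, fell to 1.01 ± 0.29 CPM (-7.53 ± 1.06) and VIM to 8.49 ± 2.4 CPM (-4.98 ± 0.62). Of the panel, 9 genes rose, 9 fell and 2 did not pass, CCND1 (0.22 ± 0.71) and CCNE1 (-0.38 ± 0.42).

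Luminal lineage genes rose in 16 of 22 cases and fell in 3 (the same adjusted over the list alone, adjusted p = 7.19e-08, and adjusted p = 0.00497 with an estimated correlation), with AGR2, a protein disulphide isomerase gene, at 346 ± 59 CPM. Of 20 oestrogen receptor targets 2 rose and 11 fell, led by IGFBP4 (-6.15 ± 1.02) and GREB1 (-5.45 ± 0.64), so that this list and the luminal list moved apart (adjusted p = 0.0022, and adjusted p = 0.381 with an estimated correlation). Basal and myoepithelial genes fell in 18 of 22 cases, with 1 rise (adjusted p = 2.23e-07), and genes of the mesenchymal programme in 14 of 18 (adjusted p = 2.25e-07). For both, the adjusted p was 0.271 with an estimated correlation. CDH2, which encodes N-cadherin, had 2 counts in the 3 libraries of line D, 5036-fold lower than in the other lines (1394 to 41589). Of 16 apocrine genes 7 rose, among them TFAP2B, a transcription factor gene, at 77 ± 3 CPM (adjusted p = 0.0158, and adjusted p = 0.587 with an estimated correlation). Counts adjusted over the list alone were 2 and 11 for the oestrogen receptor targets, 1 and 18 for the basal list, none and 14 for the mesenchymal programme and 8 and none for the apocrine genes.

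Further list changes in line D were falls of interferon response genes (2 of 21 rose and 12 fell, adjusted p = 0.0406), hypoxia and glycolysis genes (4 of 18 rose and 9 fell, adjusted p = 0.0321), fibroblast markers (2 of 16 rose and 9 fell, adjusted p = 0.0111) and ribosomal protein genes (1 of 24 rose and 13 fell, adjusted p = 0.00197), and a rise of mitochondrially encoded genes (7 of 13, adjusted p = 0.0331). With an estimated correlation their adjusted p was 0.802, 0.454, 0.454, 0.802 and 0.802. Adjusted over the list alone these counts were the same except for 13 falls of interferon response genes and 14 of ribosomal protein genes. Without line A all 5 and the apocrine list lost their calls, at adjusted p of 0.0672, 0.316, 0.0617, 0.0672, 0.253 and 0.0672. Without line A replicate 2 the apocrine list (adjusted p = 0.0776), the fibroblast markers (0.059) and the interferon list (0.266) lost theirs, and the mitochondrial list did so without line A replicate 1 (0.0628), line C replicate 3 (0.0572) or line D replicate 3 (0.0647). The interferon list was also lost without line C replicate 3 (0.0572), line D replicate 2 (0.0566) or 3 (0.0647) or line E replicate 3 (0.0514), and the hypoxia list without line C replicate 2 (0.0548), line D replicate 3 (0.065) or line E replicate 3 (0.0514). With a minimum mean of 5 CPM the interferon (0.128), hypoxia (0.0956), mitochondrial (0.0735) and fibroblast (0.0636) lists lost their calls. MALAT1 took 2.559%, 1.715% and 4.065% of counts in the line D libraries, against at most 0.725% in lines A and E. RN7SL2 took 1.182% to 1.604% in line D, below the 2.42% of line A replicate 2. Whether such differences in library content bear on the ribosomal and mitochondrial lists in line D was not tested.

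FOXR1, a forkhead transcription factor gene (ENSG00000176302, chromosome 11, 118971707 to 118981291, plus strand), led the rises in line D at 48.1 ± 8.8 CPM, 2300-fold above the pooled other lines (1115 to 5723). OTOR at 10.7 ± 1.7, the defensin gene DEFB1 47.2-fold above the pooled other lines, the receptor gene VIPR2 at 50.7 ± 8.9, RPRM at 45.2 ± 9.8, CYP4F8 at 26.2 ± 8.9 and AOC1 at 47.2 ± 11.0 CPM followed, and GP2 stood 199-fold above the pooled other lines (172 to 231). ZNF135, ZNF300 and CPNE8 had 0 counts in line D and were at least 478-fold, 798-fold and 1292-fold lower than in the other lines, and HIST1H4F and PKIA had 1 count each. In all, 4753 genes rose and 4615 fell, a total of 9368. Without line D replicate 1 the total was 6186, and without line A it was 10287.

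Line E showed a basal and mesenchymal expression pattern. VIM reached 4810 ± 880 CPM (SD, n = 4, log2 fold change 7.21 ± 0.49, edgeR adjusted p = 7.49e-07), KRT5 1020 ± 230 CPM (5.79 ± 0.68), EGFR 356 ± 78 CPM (4.02 ± 0.38) and SOX10, a neural crest transcription factor gene, 84.3 ± 8.2 CPM (6.09 ± 0.90). GATA3 fell to 1.43 ± 0.54 CPM (-5.63 ± 0.33), and CDH1, which encodes E-cadherin, stood at 347 ± 26 CPM (-1.02 ± 0.17). PGR reached 66.8 ± 9.5 CPM (3.86 ± 0.23) although ESR1 was at 4.5 ± 2.0 CPM. KRT14 did not pass (-0.46 ± 0.71), and without line A it was higher in line E than in lines C and D (2.56, adjusted p = 0.00123). Its levels were low in each of these lines, at 0.916 ± 0.463 CPM in line E, 0.437 in line C and 0.0491 in line D, scaled over all 19 libraries. Of the panel, 9 genes rose, 9 fell and 2 did not pass, KRT14 and CCNE1 (0.45 ± 0.37). CCNE1 passed without line A (1.20, adjusted p = 0.0108), but its mean in line E was raised by replicate 3. It stood at 40 CPM there, against 11.2 to 14.7 in the rest of the line.

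Of 22 basal and myoepithelial genes 18 rose in line E (18 rose and 1 fell adjusted over the list alone, adjusted p = 6.82e-08), among them MIA at 87 ± 36 CPM (7.49 ± 0.45). Genes of the mesenchymal programme rose in 13 of 18 cases (13 adjusted over the list alone, adjusted p = 6.82e-08), including CDH2 (chromosome 18, 27950966 to 28177446, minus strand) at 229 ± 44 CPM, 65.4-fold above the pooled other lines, and AXL, a receptor kinase gene, at 97.3 ± 46.0 CPM. With an estimated correlation the adjusted p was 0.211 for both. Luminal lineage genes rose in 4 cases and fell in 15 of 22 (the same adjusted over the list alone, adjusted p = 1.35e-05, and adjusted p = 0.0219 with an estimated correlation). No interferon response gene rose and 13 of 21 fell (13 adjusted over the list alone, adjusted p = 0.00016), and 9 of 14 antigen processing genes fell (9 adjusted over the list alone, adjusted p = 0.00203). For both, the adjusted p was 0.664 with an estimated correlation. CD74, the invariant chain gene, stood at 0.0419 ± 0.036 CPM. Of 16 fibroblast markers 11 rose and 1 fell, with the receptor gene PDGFRA at 124 ± 78 CPM (adjusted p = 0.00109, adjusted p = 0.38 with an estimated correlation, and 0.0889 without line A replicate 1). Ribosomal protein genes rose in 17 of 24 cases (adjusted p = 0.00016), mitochondrially encoded genes fell in 11 of 13 (adjusted p = 0.00109), proliferation genes rose in 12 of 24 (adjusted p = 0.029), and the ERBB2 neighbourhood rose in 2 and fell in 8 of 14 cases (adjusted p = 0.046). With an estimated correlation each of these 4 lists had adjusted p = 0.664. Adjusted over the list alone these counts were the same except for 13 falls of mitochondrial genes and 9 in the ERBB2 neighbourhood. Replicate 3 of line E had 0.08% of its counts in mitochondrial mRNA, against 0.26% to 0.55% in the other 3 libraries. The proliferation list lost its call without line C replicate 2 (adjusted p = 0.0619) or line E replicate 3 (0.051) and with a minimum mean of 5 CPM (0.0885), and the ERBB2 list without line C replicate 2, line D replicate 1 or 2 or any of the 4 libraries of line E (0.0502 to 0.0921).

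POU3F2, a neural transcription factor gene (ENSG00000184486, chromosome 6, 98834592 to 98839470, plus strand), stood at 168 ± 23 CPM in line E, 3413-fold above the pooled other lines (2034 to 6244). COMP, a cartilage matrix protein gene (chromosome 19, 18782773 to 18791314, minus strand), reached 1640 ± 300 CPM, 849-fold above them (780 to 925). The neural crest gene PAX3 at 13.7 ± 2.9 CPM, the neutrophil elastase gene ELANE at 158 ± 140, HMSD, TRIM43, SLITRK3 and SUN3 also rose. ATF7IP2 and PIP had 0 counts in line E, at least 617-fold and 434-fold lower than in the other lines, OAS1, an antiviral enzyme gene, was 1663-fold lower (650 to 6106) and ATXN1L 921-fold lower (500 to 1920), and CRACR2A and LTF fell as well. In all, 6676 genes rose and 5262 fell. Without line A the total was 14299 in place of 11938, and without line A and the Lucs library it was 14671.

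Line A had basal keratins and MYC at high levels, with wide spread between its 2 libraries. KRT14 (chromosome 17, 41582279 to 41586921, minus strand) stood at 83.8 CPM, with a larger SD (n = 2, log2 fold change 8.19 ± 0.65, edgeR adjusted p = 5.63e-06) and KRT17 at 393 ± 500 CPM (SD, 7.93 ± 0.76). MYC was at 220 ± 1.6 CPM (3.18 ± 0.19), VIM at 1290 ± 810 CPM (4.68 ± 0.43), and PGR at 0.102 ± 0.022 CPM (-8.63 ± 0.49). Of 22 basal and myoepithelial genes 18 rose (19 adjusted over the list alone, adjusted p = 7.81e-16, and adjusted p = 0.0405 with an estimated correlation). Of 22 luminal lineage genes 2 rose and 16 fell (3 and 16 adjusted over the list alone, adjusted p = 8.4e-11, and adjusted p = 0.00181 with an estimated correlation). Hypoxia and glycolysis genes rose in 10 of 18 cases (11 adjusted over the list alone, adjusted p = 2.85e-05, and adjusted p = 0.123 with an estimated correlation), among them the carbonic anhydrase gene CA9 at 187 ± 250 CPM. MYO3A had 0 counts outside line A and was at least 2359-fold higher there. GPR12, SPESP1, LPL, CRMP1, ACAN, GRIN2A and GFAP rose and LIN7A, SNRPN, M1AP and ANXA9 fell, and LIN7A was 832-fold lower than in the pooled other lines (453 to 1736).

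Other lists called in line A were ribosomal proteins (19 of 24 rose), proliferation (12 of 24 rose), G1 to S regulators (7 of 14 rose), the MYC programme (9 of 16 rose), the mesenchymal programme (10 of 18 rose and 1 fell), interferon response (16 of 21 rose), oestrogen receptor targets (2 of 20 rose and 6 fell), apocrine genes (2 of 16 rose and 3 fell), p53 targets (1 of 20 rose and 5 fell) and mitochondrially encoded genes (1 of 13 fell), at adjusted p of 7.89e-08 to 0.0253, and adjusted p = 0.182 to 0.66 with an estimated correlation. Adjusted over the list alone, 21 ribosomal protein, 14 proliferation, 10 MYC programme, 11 mesenchymal and 17 interferon response genes rose and 10 oestrogen receptor targets fell, with the other counts unchanged. Without line A replicate 2 the interferon list pointed down (adjusted p = 0.0126), and the ribosomal (0.0849), mesenchymal (0.084), MYC (0.171) and apocrine (0.593) lists lost their calls. Without line A replicate 1 the mitochondrial (0.151) and p53 (0.238) lists lost theirs, and SOX10 moved from 5.64 to -0.23. In all, 4804 genes rose and 1906 fell.

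The other 11 lists were called in none of the 4 lines (camera adjusted p of 0.0732 or more). They were epithelial junctions, cholesterol synthesis, cancer-testis antigens, secretory and mammary differentiation, immediate early genes, heat shock and unfolded protein genes, and the markers of endothelium, myeloid cells, T and natural killer cells, B and plasma cells and adipocytes. Leaving out 1 library called the cancer-testis antigens in line D without any library of line C (0.0287 to 0.0334) and in line C without line C replicate 1 (0.00107), the heat shock list in line C without line A replicate 1 (0.0187) or line D replicate 3 (0.0492), the B and plasma cell markers in line D without line C replicate 2 (0.0102), and the immediate early genes in lines A and D without line D replicate 3 (0.0163 and 0.0364). Few immune markers had enough counts to be tested, 5 of 15 for myeloid cells, 5 of 18 for T and natural killer cells and 6 of 13 for B and plasma cells.

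Luc2 libraries were compared with untagged libraries of the same lines. In each line the untagged library also carried a lower number in its label than the Luc2 libraries. The labels do not say what this number marks, so the tag and whatever it marks cannot be told apart. No gene passed (edgeR, 0 of 20812 at adjusted p under 0.05, 731 at an unadjusted p under 0.05), and DESeq2 called 22, all lower with Luc2. ESR1 (-0.04 ± 0.30), MKI67 (0.22 ± 0.22), MYC (0.17 ± 0.17) and VIM (-0.45 ± 0.64) gave small differences, KRT5 one of -2.06 ± 0.72. In lines C and E alone edgeR called 0 genes, with 860 at an unadjusted p under 0.05, and DESeq2 called 24. A difference of the Luc2 effect between lines C and E was tested as an interaction (edgeR, 0 of 21274 genes, 1018 at an unadjusted p under 0.05; DESeq2 was not run on it). With 1 untagged library in each of these lines, their Luc2 fit recovered 0% of simulated 4-fold changes, so neither count of 0 shows that there was no difference. No list member passed over all genes, and adjusted over the list alone 6 mitochondrially encoded genes fell and 1 myeloid marker rose. With the preset correlation 9 lists were called. The interferon response (adjusted p = 2.07e-11), mitochondrially encoded (-0.70), mesenchymal, basal, antigen processing, fibroblast and B and plasma cell lists were lower with Luc2, and the immediate early and histone lists were higher. All lost their calls with an estimated correlation (adjusted p = 0.433 to 0.629). All but the interferon and mesenchymal lists also lost their calls (adjusted p = 0.0506 to 0.64) without 1 or more of line A replicates 1 and 2, line C replicates 1, 2 and 3 and line E replicate 2. The ribosomal protein list was not called with all libraries (camera adjusted p = 0.172, median log2 fold change -0.23). Its median was -0.34 without line C replicate 1 and -0.64 without replicate 2. It was 0.26 and 0.25 without line A replicate 1 or 2, and 0.25 in lines C and E alone. These last settings are in effect the same fit, since line A without either library adds nothing to the Luc2 difference. Likewise, line C replicate 2 and line E replicate 2 are the only untagged libraries of their lines. Leaving out either takes the whole line out of the difference, not 1 library. Without line A replicate 2 the number of lists called was 15, and without line E replicate 2 it was 3.

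Marker levels across all 10 lines gave the wider setting. ESR1 stood at 478 ± 157 CPM (SD, n = 3) in line C, 548 in line F and 705 in line H, and at 33.9 or less in the other 7 lines. PGR was high in line F at 1026 and in line C at 184 ± 29, but stood at 1.96 in line H. ERBB2 ranged from 198 ± 39.2 in line E to 700 in line I. KRT5 reached 5249 CPM in line B, 821 in line G and 1010 in line J, and KRT14 1821 in line G. VIM was at 700 in line B, 1522 in line G, 534 in line F and 661 in line J, but at 22.3 and 31.3 in lines H and I. These differences between single libraries have no replicate check.

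**Figure D2:**
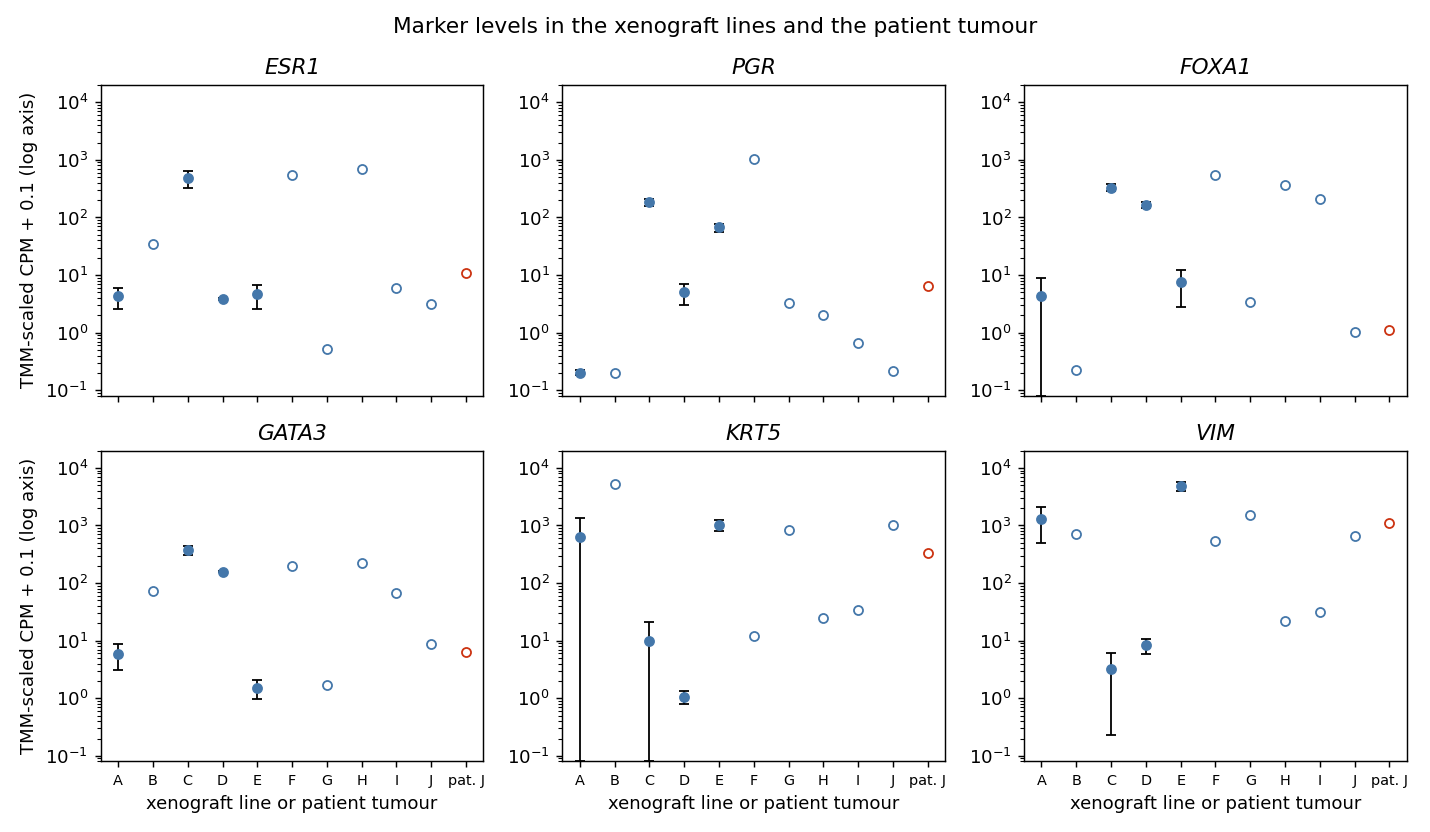
Levels of ESR1, PGR, FOXA1, GATA3, KRT5 and VIM in the 10 xenograft lines (blue) and the patient tumour of line J (red), as TMM-scaled CPM + 0.1 on a log axis. Filled points with bars are means ± SD over the libraries of a replicated line, with a bar cropped at the lower axis where the SD exceeds the mean, and open points are single libraries; ESR1 exceeds 400 in lines C, F and H only.

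The patient tumour of line J was set beside the xenograft of that line, to see which transcripts were carried into the mouse. Genes of human connective tissue, vessels, fat and immune cells were higher in the patient tumour than in the xenograft, where many of them had few counts or 0. COL3A1, a fibrillar collagen gene, stood at 3669 CPM against 1.32, a ratio of 2771 (95% interval 2071 to 3799). LYZ, the lysozyme gene, stood at 1196 against 0.118 CPM, with 4 counts in the xenograft, and CD74 at 1661 against 1.03. DCN had 18657 counts against 3, a ratio of 7023 (2403 to 34059). COL1A2, LUM, COL6A3 and CYBB completed the largest rises. Not all such genes were scarce in the xenograft, as COL1A1, named after its values were seen, stood at 2737 against 240.0 CPM. FABP4 and ADH1B, fat cell genes, had 0 counts in the xenograft and were at least 1569-fold and 2228-fold higher in the tumour, and JCHAIN, a plasma cell gene, at least 1529-fold. Median log2 ratios were 6.79 for macrophage and myeloid markers, 6.18 for adipocyte markers, 5.89 for fibroblast markers, 4.47 for endothelial markers, 4.26 for T and natural killer cell markers and 2.25 for B and plasma cell markers, each at percentile 100 of 10000 matched random lists. The mesenchymal programme (1.62, with 8 of 18 genes at least 4-fold higher) and the immediate early genes (0.88, with 5 of 17) also stood at percentile 100, and antigen processing (0.58) at 99.99.

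The keratin genes named here and the medians of the epithelial junction and basal lists were lower in the patient tumour than in its xenograft. Of the members of these lists, 5 of 18 and 2 of 22 were at least 4-fold lower. CPM are shares of a library's counts, so these falls need not be changes within tumour cells, which was not tested. KRT83 and KRT75, keratin genes, stood at 1.73 against 111 CPM and at 14.5 against 340 CPM, and S100A2, a calcium-binding protein gene, at 5.68 against 237, 41.7-fold lower. LINC01235, NANOS1, SLC6A2, CAPN6 and SBSN were 25.3-fold, 21.3-fold, 17.3-fold, 14.8-fold and 13.6-fold lower. KRT5 stood at 336 against 1010 CPM, KRT17 at 144 against 659 and CDH1 at 171 against 605. The panel genes PGR (53.1-fold, 20.4 to 197), SOX10 (10.5-fold, 6.97 to 16.4) and ESR1 (3.54-fold, 2.83 to 4.47) were higher in the patient tumour, and 3 of 22 basal and 3 of 22 luminal genes were at least 4-fold higher. Median log2 ratios were -1.82 for cholesterol synthesis, -1.64 for epithelial junctions, -1.43 for ribosomal proteins and -1.41 for basal genes, each at percentile 0 of the matched random lists. The proliferation list had a median of -1.02 (percentile 0.01) and the histones one of -1.26 (percentile 0.05), while MKI67 stood at 287 against 330 CPM. The luminal list had a median of -0.62 (percentile 1.32) and the G1 to S regulators one of -0.92 (percentile 0.8), while the apocrine list had one of 0.39 (percentile 98.43). Of 28597 genes, 1651 were at least 4-fold higher and 302 at least 4-fold lower in the patient tumour. With CPM + 5 these counts were 614 and 97, and with library size alone 181 were lower. The median log2 ratio of all genes was 0.03 and the libraries correlated across genes at r = 0.916. This comparison rests on 1 library of each kind, without a replicate check, and describes these libraries.

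**Figure D3:**
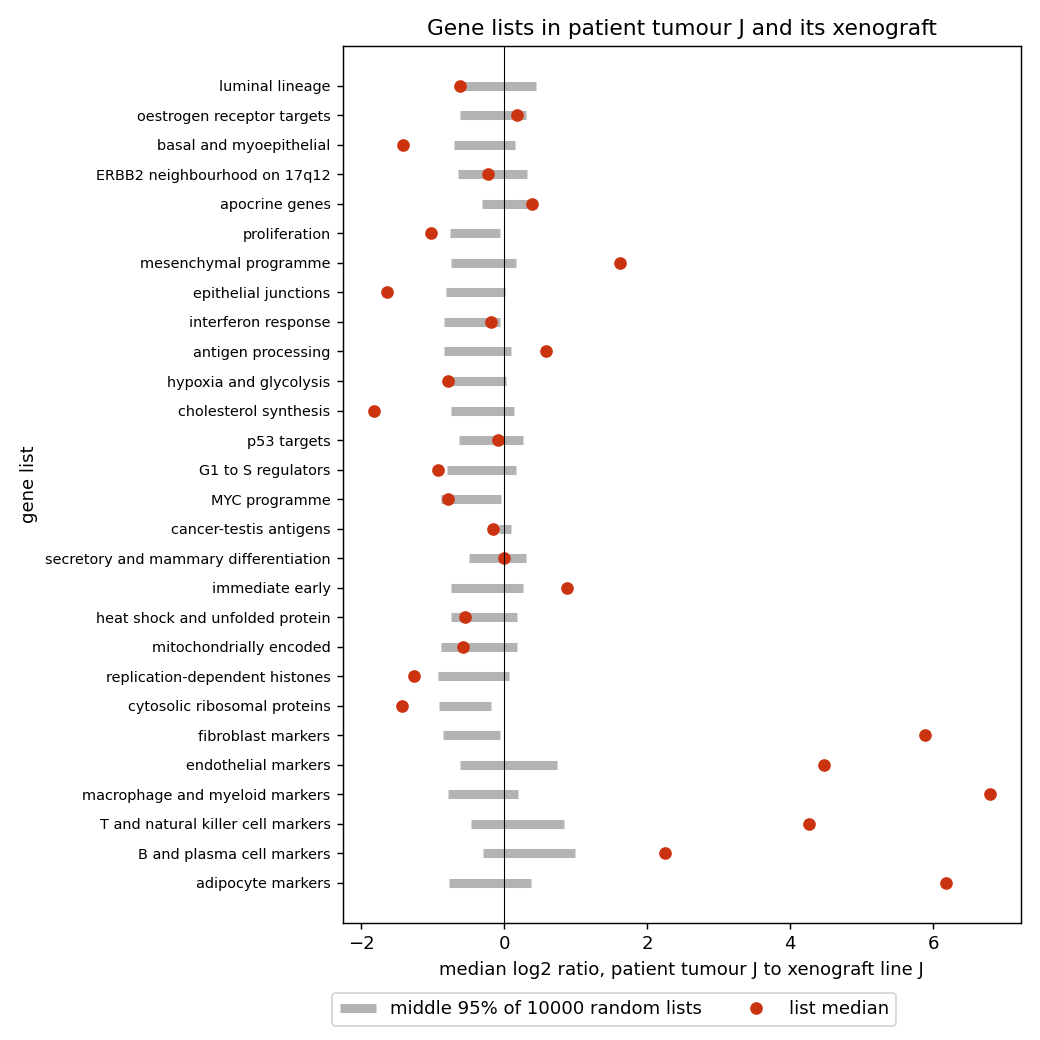
Median log2 ratio of each gene list between patient tumour J and xenograft line J (red points), with the middle 95% of 10000 random lists of the same size matched on expression (grey bars). The 6 lists of fibroblast, endothelial, myeloid, T and natural killer cell, B and plasma cell and adipocyte markers lie far to the right of their bars, at 2.25 to 6.79.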

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

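Tests on replicate 3 of line E for cells of another type and for the sample type were chosen only after the result they measure had been seen. Among 54 measures of the 4 line E libraries (the panel, gene list means and similar), 10 had 1 library far from the other 3, and 8 of these were replicate 3. Chance flags about 1 in 20 such groups. In replicate 3, EGFR stood at 233 CPM (387 to 415 in the others) and CCNE1 at 40 (11.2 to 14.7). Its mean log2(CPM + 1) was 7.75 for cholesterol synthesis genes (5.55 to 5.78), 5.51 for p53 targets (4.74 to 4.86), 4.15 for apocrine genes (3.51 to 3.54), 3.47 for secretory genes (2.54 to 2.61), 1.63 for adipocyte markers (1.09 to 1.18) and 0.454 for B and plasma cell markers (0.366 to 0.378). In replicate 4, the luminal mean was 4.61 (4.77 to 4.79) and the hypoxia and glycolysis mean 7.1 (6.74 to 6.77).

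Replicate 3 correlated with the other 3 line E libraries at a mean r of 0.965, while those correlated at 0.993 with each other. Compared with them, its cholesterol synthesis genes had a median log2 ratio of 2.03 and its mitochondrially encoded genes one of -2.15. The tables argue against depth as the source, since thinning to 30943593 counts left the mean r at 0.964. Leaving out the 10 highest genes of each library, 15 genes in all, also left it at 0.964. So few genes weigh little in an r over all genes. This result therefore cannot decide whether a few abundant genes were the source. Human connective tissue, vessel, fat or immune cells would bring their markers, but the highest median log2 ratio among 6 such lists was 0.15, for adipocyte markers. The medians of the immune lists were 0.00, and few immune markers had enough counts to show a change. These lists hold no markers of other epithelial or tumour cells, so they cannot decide whether such cells were present. The label of this library alone names Lucs and cells; with 1 such library, an effect of the sample type and of the library cannot be told apart, and either may be the source.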

How the results depend on the processing

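The fits without line A, without line A and the Lucs library, and of lines C and E only were chosen after the data had been seen; the other settings were fixed before. No paired analysis was possible because replicate numbers of different lines mark no shared animal or batch, and each number is nested in its line. Of the values for comparisons, 204 kept their direction and side of the threshold or stayed within 1.5 times, as did 1991 list tests and 5701 values for named genes, while 110 values for named genes and 121 list tests lost their call and 11 and 49 gained one. Of marker levels 179 moved and 261 did not, and of the patient comparison's list medians 51 moved and 88 did not. Where a left-out library leaves line A, or the Luc2 libraries of line C or E, with 1, that library is assumed to vary like the other groups. Line A has 1 library of each kind for Luc2, and lines C and E have 1 untagged library each. Leaving out such a library leaves its line without a Luc2 comparison, and the fit then rests on the other lines. The lowest and highest numbers of Luc2 lists called below come from such fits. DESeq2 gave no adjusted p for GTSF1 in line C and LTF in line E. Where no cause is given below, the cause was not tested.

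With a minimum mean of 5 CPM fewer genes were tested, and 10438 differed among lines, 7259 in line C and 7610 in line E, with 6 lists called in line D. A test against a 2-fold change, which asks for more, gave 2809 genes in line A, 5738 in line C, 4066 in line D and 5719 in line E. With an estimated correlation 2 lists were called in line A, 2 in line C, 1 in line D, 1 in line E and 0 for Luc2. Without line A 5 lists were called in line D, and 6 without line A and the Lucs library. DESeq2 called 22 genes for Luc2, and 24 in lines C and E only, where 14 lists were called. Leaving out single libraries moved the line D count between 6186 and 10790 genes, and the Luc2 lists between 3 and 15. Without Luc2 and Lucs libraries the similarity difference was 0.150, no longer past the threshold because 6 libraries allow no smaller p than 0.05. Its pairs within lines were those of line D alone. In the patient comparison CPM + 5, which shrinks low genes, left 614 genes higher and 97 lower, and library size alone left 181 lower.

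Some results changed direction, among them the ribosomal protein list for Luc2. Its median log2 fold change was negative or positive depending on which libraries were left out. Over the fits that left out 1 library each, the interferon list in line A had adjusted p of 6.42e-12 to 0.0179, and 0.0126 in the other direction without replicate 2. Log2 fold changes in line A ranged from -0.23 to 6.65 for SOX10, from -3.50 to 4.85 for XAF1 and from -1.99 to 4.81 for IFIT1. KRT14 in line E became positive at 2.56 without line A and at 2.24 without line A and the Lucs library, and CCNE1 in line D became positive at 0.55 in the latter. Without a filter on low counts the median log2 fold change of all genes was -0.191 in line C and -0.302 in line D, against -0.002 and -0.041, and it was 0.108 in line A in the main setting, so changes of that size carry no direction. The effect of depth on the line comparisons was not tested. In simulated data 4% to 10% of 2-fold changes between lines were recovered and 1% for Luc2, and in lines C and E only 0% of 4-fold changes. Far fewer genes changed in these data than passed in the real line comparisons, so the shares for lines need not hold there.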

Other observations

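The tests of the patient tumour were chosen only after the result had been seen, and the genes of this paragraph after their values were seen. Lines B, F, G, H and I, with 1 library each, carried genes at levels well above those of the other lines. In line B, the matrix proteoglycan gene VCAN stood at 5764 CPM, OLFM4 at 2316, CYP1B1, a cytochrome P450 gene, at 2383, and SPARCL1, SLCO1A2 and ADGRL3 at 1736, 1520 and 1708, the last against at most 60.4 in any library of the other lines. In line F, CALCR, the calcitonin receptor gene, stood at 203 CPM (at most 0.714 in the other lines), BMPER at 335 (at most 6.95) and the mucin gene MUC2 at 250 (at most 17.3). Line G had the contractile genes TAGLN at 1924 and ACTA2 at 1736 CPM, and A2M at 2544. Line H had CHGA, the chromogranin A gene of neuroendocrine cells, at 3767 CPM (at most 10.2 in the other lines) and the matrix protein gene MGP at 14773 (at most 3761). Line I had CEACAM5, a carcinoembryonic antigen gene, at 671 CPM (at most 20.2) and KRT24 at 321 (at most 0.74).

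Random regroupings of the 12 libraries of lines A, C, D and E into groups of the same sizes tested whether chance could give the gene counts of the line comparisons. In 50 groupings, the real one included, only 1, the real one, reached the count in each of the 5 results. So few groupings cannot exclude chance. Libraries of a line were already seen to resemble each other, so lower counts in mixed groups could be foreseen. Nor can the regroupings tell the line from a batch or a mixed-up library as the source. The real counts were 17528 among lines, 6710 for line A, 11449 for line C, 9368 for line D and 11938 for line E, and the highest others were 4495, 425, 45, 965 and 6381. For Luc2 the 18 groupings within lines gave 0 genes at most, as did the real one, and are too few for a share under 0.05.

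Ribosomal protein genes were lower in line C, whose libraries also gave large shares to RN7SL2 and MALAT1. A few abundant RNAs as the source were predicted to leave little after rescaling, but with library sizes from protein-coding genes the list median was still -1.57, from -1.81. Protein-coding genes took 76.0% to 83.2% of counts in the line C libraries, and larger shares in lines A, D and E. With such shares the rescaling can move genes only slightly, so a median that stayed low could be foreseen. This result therefore cannot decide whether a few abundant RNAs were the source. Gene length or GC content would move genes matched on both, and 447 such genes had a median of -0.35, close to the bound of -0.45 set beforehand, so a minor part may come from it. Differences of the line itself, and of RNA extraction or storage, stay open and were not tested.

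Genes of connective tissue, vessel, fat and immune cells were higher in the patient tumour than in its xenograft. The tables argue against scaling between the 2 libraries, since a scale factor moves all genes alike and the lowest of the 6 list medians still lay 2.22 (log2) above the median of all kept genes. Human cells of other types in the patient tumour, replaced by mouse cells in the xenograft, are a candidate explanation that stays open: all 6 marker lists stood at percentile 100 of the matched random lists, but this restates the pattern and cannot support an explanation of it. Abundant genes among those higher in the tumour were COL3A1 at 3669, COL1A2 at 3133, COL1A1 at 2737 and COL6A3 at 1839 CPM. None of these lists shares a gene with another, but xenografts also express some members, since 16 of 18 fibroblast, 10 of 14 endothelial and 10 of 13 adipocyte markers had enough counts in lines A, C, D and E to be tested. How far tumour cells give these transcripts, and how mouse reads were treated, which is not given in the sources used here, stay open.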
